A study of Mus musculus with 8 samples.

How the data were processed

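The data are RNA-seq read counts from sorted mouse LSK cells (lineage-negative, Sca-1 positive, c-Kit positive bone marrow cells, strain C57BL/6), 3 libraries from AML1/ETO mice and 5 from wild-type controls, grouped by the genotype and title in the labels. Per the labels' protocols, mice were given 4 injections of poly(I:C), each of 5 mg/kg and on alternate days, cells were sorted 4 weeks later, RNA was extracted with RNAiso Plus, and libraries were made with a NEBNext Ultra RNA kit. The deposited values are raw counts per Ensembl gene, with a column per library and no pooling. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build mm10. The annotation release, the strand setting and the handling of duplicates and of reads with several alignments are not given in the sources used here. Those choices decide how reads of overlapping genes and of near-identical copies were assigned.

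The deposited table held 54532 gene identifiers, of which 32927 were at 0 in every library. Symbols and coordinates came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes; 54495 identifiers matched and 37 did not. Library totals ran from 14693080 to 17527043 reads. No sample column was left unused.

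Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which left 15009, libraries were scaled with TMM factors, and the quasi-likelihood test (glmQLFit, glmQLFTest) compared AML1/ETO with control over all 8 libraries without covariates. The test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 72.6%. Printed CPM values use the TMM-scaled library sizes, and standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. A group at 0 reads in all its libraries was given a floor of 3 counts per library, and the fold is then written as at least that large. Folds of means without a library keep the scaling of all 8.

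Before the data were examined, 23 gene lists were fixed, 9 of them markers of cells that the sort gate could let in, together with the tests, the alternatives and the rule for naming genes. Some genes are in more than 1 list. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 23 lists. Alternatives for lists were a correlation estimated per list and fry, which asks whether a list's own genes move, on balance, in 1 direction. The naming rule took Runx1, Runx1t1, Cbfb and Ikzf1 to Ikzf5 always; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of 5 CPM or more and every AML1/ETO library beyond every control, leaving out unnamed gene models, pseudogenes, immunoglobulin and T cell receptor segments and sex-linked markers; and up to 4 members per list by smallest p. Some genes that the rule took are not reported here. Other members of the lists are named where they help to describe a list, and these were chosen after their values were seen.

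Alternatives for genes were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors, library totals alone, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, each library left out in turn, a 2-fold minimum and the replicate number as a block. Alternatives chosen after seeing the data left out genes on X and Y, left out both first libraries, and kept genes with a mean of 20 CPM or more. All 56 ways to set 3 libraries against 5 were also run.

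The procedure was tested on simulated counts for the same 15009 genes with a seeded set of changed genes. The edgeR test recovered 24%, 56%, 68% and 80% of genes changed 2-, 4-, 8- and 16-fold, and 3.1% of its calls were unchanged genes, against 33.8% for DESeq2 and 4.72% for limma-voom. A list simulated as 4-fold lower was called by camera with the preset and the estimated correlation and by fry, and none of 22 unchanged lists was. Genes were drawn independently of each other, so the simulation cannot show how often lists of correlated genes are called wrongly. The spread of each simulated gene was edgeR's own estimate, so the comparison between tools is not neutral. Only 50 genes were changed at each fold and 14787 were unchanged, whereas 3862 genes were called in the data. Each gene also had the same spread in both groups. Recovery and the share of false calls may therefore differ in the data.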

Results

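RNA was sequenced from mouse bone marrow LSK cells, the lineage-negative fraction positive for Sca-1 and c-Kit that holds the haematopoietic stem cells and early multipotent progenitors. There were 3 libraries from mice carrying AML1/ETO, the RUNX1-RUNX1T1 fusion that the t(8;21) translocation creates in acute myeloid leukaemia, and 5 from wild-type control mice. All mice had received 4 injections of poly(I:C), a double-stranded RNA analogue that raises interferon, at 5 mg/kg, and the cells were sorted 4 weeks later. The AML1/ETO libraries held 14693080, 16433454 and 16321717 counted reads and the control libraries 16374232 to 17527043. Between 13446 and 14284 genes had a read in the AML1/ETO libraries and between 13660 and 17131 in the controls. The first principal component of log2 normalised counts, with 44% of the variance, separated the groups. The second, with 14.3%, set AML1/ETO library 1 and control library 1 apart from the other 6 libraries. Of genes with 20 to 50 reads expected from the other libraries of their group, 42.3% to 50.7% were at 0 reads in the AML1/ETO libraries and 46.0% in control library 1. In controls 2 to 5 the share was 11.0% to 26.7%. Limits drawn from a count of 0 therefore cover counting error only. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples.

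**Figure D1:**
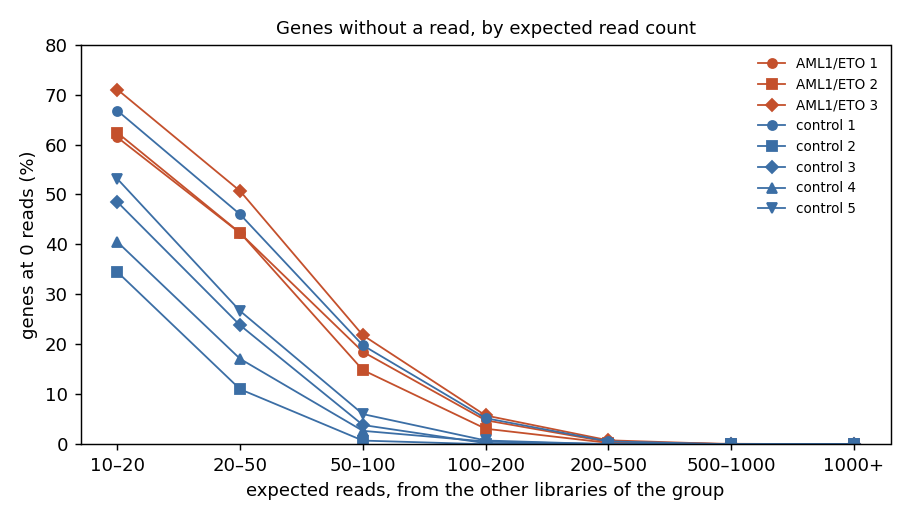
Percentage of genes at 0 reads in each library (vertical axis) against the read count expected from the other libraries of the same group (horizontal axis, classes of expected reads), with a line per library. In the class of 20 to 50 expected reads the 3 AML1/ETO libraries and control 1 lie between 42.3% and 50.7%, and controls 2 to 5 between 11.0% and 26.7%.

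The comparison of AML1/ETO with control LSK cells asked which genes differ with the fusion, and the series names Ikzf2 as its target. Runx1t1 and Ikzf2 were higher in all 3 AML1/ETO libraries than in any control library, as were genes of the immediate early response (Jun, Fos, Dusp1), the NF-kappaB response (Tnfaip3, Cxcl2) and mast cells (Cpa3, Cma1). Genes of DNA replication and mitosis (Mcm5, Rrm1, Mki67), the myeloid regulators Spi1, Cebpa and Csf1r, and several lymphoid genes (Ighm, Rag1, Tcf7) were lower. In all, 1734 of 15009 tested genes rose and 2128 fell, 1213 and 1468 of them by 2-fold or more (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The risen genes made up 44.9% of those that changed, 34.2% when libraries were scaled by their totals alone and 49.9% with DESeq2 size factors. These scalings shifted the median log2 fold change of all genes by −0.146 and 0.066.

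Runx1t1 (ENSMUSG00000006586, chromosome 4, 13743436 to 13893649 in mm10) encodes the ETO part of the fusion. It stood at 94.1 ± 36.0 CPM (normalised read counts; SD, n = 3) in the AML1/ETO libraries and 3.78 ± 2.72 CPM (SD, n = 5) in the controls. This was a 24.9-fold rise (log2 fold change 4.64, SE 0.52, adjusted p = 7.66e-05). Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149), the other fusion partner, stood at 212 ± 87.3 CPM against 151 ± 29.1 CPM and did not pass the test (log2 fold change 0.49, SE 0.26, adjusted p = 0.187). Without AML1/ETO library 1 it passed, at 0.78 (adjusted p = 0.00932, the lowest of a range up to 0.627 over the alternatives). Cbfb, the cofactor that stabilises RUNX proteins on DNA, had a log2 fold change of −0.56 (SE 0.23, adjusted p = 0.0960), and passed at −0.97 without AML1/ETO library 2 (adjusted p = 0.00219, in a range up to 0.266 over the alternatives). The sequence of the AML1/ETO allele is not given in the sources used here, so reads of the fusion that align to mouse Runx1t1 or Runx1 were counted with the native genes.

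Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245) encodes the Ikaros-family zinc finger factor Helios. It stood at 196 ± 52.3 CPM (SD, n = 3) in the AML1/ETO libraries, from 148 to 252 CPM. The controls stood at 28.9 ± 3.38 CPM (SD, n = 5), from 24.0 to 32.5 CPM. It rose 6.79-fold (log2 fold change 2.76, SE 0.20, adjusted p = 2.61e-06). Of the other Ikaros-family genes, Ikzf1 had a log2 fold change of −0.25 (SE 0.15, adjusted p = 0.263) at 292 against 347 CPM. Ikzf4 was low, at 0.218 against 1.39 CPM (adjusted p = 0.389). Ikzf5 at 3.34 against 2.68 CPM (adjusted p = 0.913) varied from 0 to 7.78 CPM between libraries. Ikzf3 had 7 reads in control library 2 and none elsewhere. In the Ikaros list 1 of 4 tested members rose, also 1 when adjusted over the list alone, and the list was not called (limma camera, adjusted p = 0.473).

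**Figure D2:**
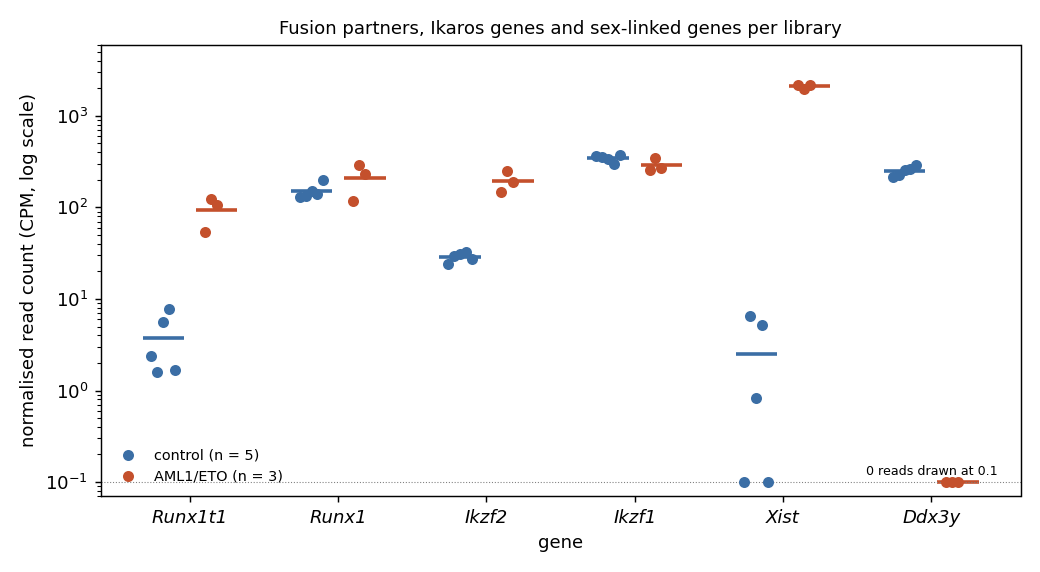
Normalised read count (CPM, log scale; 0 reads drawn at 0.1) of Runx1t1, Runx1, Ikzf2, Ikzf1, Xist and Ddx3y, with a point per library and a horizontal line at each group mean (3 AML1/ETO, 5 control). Runx1t1 and Ikzf2 are higher in every AML1/ETO library than in any control, and Xist and the Y-linked Ddx3y split the groups completely.

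The groups also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, had 28559 to 33151 reads in the AML1/ETO libraries and 0 to 111 in the controls. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no read in any AML1/ETO library. In the controls Ddx3y had 3688 to 5038 reads. It was at least 1232-fold lower in the AML1/ETO group, taking 3 reads per library as the floor. No library had the pattern of the other group, so each count and list here compares groups that differ in genotype and in these markers alike. With genes on X and Y left out, 1689 genes rose and 2056 fell.

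Among the 10 largest rises of genes that separated the groups completely were Cma1, Trnp1, Unc45b, Col13a1, Mchr1, Olfr1033, Mir7007, Myo16 and Dcpp3, all without a read in any control. Cma1, the mast cell chymase, reached 148 ± 102 CPM, at least 858-fold above the control floor, or 530-fold without AML1/ETO library 3. Unc45b, a myosin chaperone of striated muscle, reached 78.8 ± 31.4 CPM. Mir7007 lies inside Cpa3 (chromosome 3, 20215620 to 20242181) on the same strand, so its reads cannot be told from those of Cpa3. Unc45b overlaps an antisense transcript, whose reads could not be told apart if strand was not used. Among the 10 largest falls were Slc26a11, Tbxa2r, Vwf, Chac1, Art4, Irf4, Lhfpl2, Epha2 and Mn1, all without a read in any AML1/ETO library. Vwf, the von Willebrand factor that marks platelet-primed stem cells, stood at 40.3 ± 9.67 CPM in the controls and was at least 198-fold lower. Irf4, a lymphoid and dendritic transcription factor, stood at 33.2 ± 15.3 CPM and was at least 163-fold lower. Tbxa2r, the thromboxane receptor, did not pass with limma-voom (adjusted p = 0.0785, the highest over the alternatives). In all, 43 of the risen genes were at 0 in every control and 348 of the fallen genes at 0 in every AML1/ETO library. These counts are not directly comparable, since the first needs zeros in 5 libraries and the second in 3. Of genes with 20 to 50 expected reads, 42.3% to 50.7% were at 0 in single AML1/ETO libraries. In single controls the share was 11.0% to 46.0%. The gap between the counts therefore does not show that more genes were silenced than switched on.

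Immediate early genes, which cells switch on within minutes of a stimulus, rose together: 17 of 22 rose and none fell, also 17 when adjusted over the list alone. Their median log2 fold change was 2.87 (camera adjusted p = 1.11e-17; adjusted p = 0.307 with an estimated correlation). Jun rose to 7966 CPM from 400 CPM (log2 fold change 4.32). Dusp2, a MAP kinase phosphatase, rose 19.2-fold (log2 fold change 4.27, SE 0.14, adjusted p = 2.73e-08). Zfp36, an mRNA decay factor, rose 18.2-fold and Nr4a1, an orphan nuclear receptor, 9.16-fold. The heat shock genes of the list did not pass: Hspa1a had a log2 fold change of −0.39 (adjusted p = 0.772) and Hspa1b of 0.32 (adjusted p = 0.647). Of the NF-kappaB and inflammatory cytokine genes 7 of 18 rose and 2 fell, or 8 and 2 when adjusted over the list alone. This list was called higher (median log2 fold change 0.91, adjusted p = 0.00149; adjusted p = 0.307 with an estimated correlation). Tnfaip3, the A20 inhibitor of NF-kappaB, rose 31.5-fold to 4830 ± 1151 CPM (log2 fold change 4.98, SE 0.21). Cxcl2, a neutrophil chemokine, rose 21.9-fold and Nfkbia, which holds NF-kappaB in the cytoplasm, 5.90-fold. Nfkb1 fell (log2 fold change −0.93) and Ccl5 was at 0 reads in all AML1/ETO libraries.

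Among 11 tested mast cell, basophil and eosinophil genes 6 rose and 3 fell, or 6 and 4 when adjusted over the list alone. The list was called higher (median log2 fold change 3.90, adjusted p = 0.0357; adjusted p = 0.307 with an estimated correlation). The call was lost without control library 3 (adjusted p = 0.0844, in a range from 0.0109 when a library was left out), with DESeq2 size factors (0.0525) and with the 1 CPM filter (0.0532). The members moved apart. Cpa3, the mast cell carboxypeptidase, rose 269-fold to 3844 ± 2190 CPM from 14.3 ± 5.87 CPM (adjusted p = 3.74e-07). Hdc, the histamine-forming enzyme, rose 14.96-fold and Mitf, a mast cell transcription factor, 17.96-fold. In contrast, the eosinophil granule genes Prg2 and Epx and the basophil protease Prss34 were without a read in the AML1/ETO libraries. The tryptase Tpsb2 had 339, 28 and 0 reads in AML1/ETO libraries 1, 2 and 3, and Mcpt4 had 233, 0 and 0.

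Stem cell genes went both ways: 9 of 21 rose and 6 fell, or 10 and 7 when adjusted over the list alone. The list was not called (median log2 fold change 0.72, adjusted p = 0.0619). It passed without AML1/ETO library 2 (adjusted p = 0.0437) or control library 4 (0.0482), in a range up to 0.101 when a library was left out. Ly6a, the gene of the sorting marker Sca-1, rose 31.0-fold to 466 ± 395 CPM from 14.99 ± 6.10 CPM, or 15.9-fold without AML1/ETO library 3. The controls were low for Ly6a, at 8.26 to 23.4 CPM, against a mean of 431 CPM for Kit. Both groups were sorted as Sca-1 positive, and why the control RNA was this low was not tested. Kit, the other sorting marker, rose 3.22-fold to 1386 ± 416 CPM, and Gata2, a stem cell transcription factor, 3.43-fold. Kit and Gata2 are also expressed by mast cells, whose marker Cpa3 rose in the same libraries. Counts from a sorted population cannot tell a change within cells from a change in the mix of cells that passed the gate. This limit holds for the other genes and lists too. Mecom, a regulator of stem cell self-renewal, fell 5.32-fold (log2 fold change −2.41, SE 0.31, adjusted p = 0.000210). Of the haematopoietic transcription factor and RUNX complex genes 8 of 24 rose and 2 fell, with the same counts when adjusted over the list alone. The list was called higher (median log2 fold change 0.27, adjusted p = 0.0246; adjusted p = 0.307 with an estimated correlation). Without AML1/ETO library 2 the adjusted p was 0.0958, the highest of a range from 0.00176 when a library was left out. Myb, a progenitor transcription factor, rose 2.97-fold and Ldb1, a cofactor of LIM-domain complexes, 2.39-fold, and Runx3, a RUNX1 paralogue, fell 3.99-fold to 123 ± 27.4 CPM.

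Granulocyte and monocyte priming genes were called lower (median log2 fold change −2.59, adjusted p = 0.0338; adjusted p = 0.432 with an estimated correlation). In this list 11 of 20 fell and 5 rose, or 13 and 5 when adjusted over the list alone. Without control library 1, 3 or 5 the call was lost, at adjusted p = 0.0604, 0.0652 and 0.0521, in a range from 0.0120 when a library was left out. Spi1, which encodes the myeloid master regulator PU.1, fell 6.08-fold to 57.0 ± 8.07 CPM from 346 ± 45.1 CPM (log2 fold change −2.60, SE 0.18, adjusted p = 2.10e-06). Gfi1, a repressor that favours granulocytes, rose to 275 ± 41.6 from 17.2 ± 9.73 CPM (log2 fold change 4.00). Csf2rb, the shared beta chain of the IL-3 and GM-CSF receptors, rose 4.94-fold and Cebpb 5.15-fold. Lymphoid priming genes were called lower too (median log2 fold change −1.79, adjusted p = 0.0246; adjusted p = 0.307 with an estimated correlation). Here 10 of 18 fell and 3 rose, or 10 and 4 when adjusted over the list alone. Ighm, the immunoglobulin mu chain, was at least 662-fold lower, with no read in the AML1/ETO libraries against 135 ± 40.1 CPM. Tcf7 and Rag1, genes of T cell commitment and of antigen receptor recombination, were at least 60.3-fold and 60.5-fold lower. Satb1, a chromatin organiser, rose 3.08-fold.

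The neutrophil, macrophage, T and NK cell and B cell marker lists were called lower. Of 11 mature neutrophil genes 4 fell and none rose, or 6 when adjusted over the list alone (median log2 fold change −3.16, adjusted p = 0.000406; adjusted p = 0.307 with an estimated correlation). Camp, an antimicrobial peptide, fell to 0.604 from 22.9 CPM, or at least 108-fold without AML1/ETO library 2, and Cxcr2, a chemokine receptor, was at least 19.3-fold lower. Of 12 macrophage and monocyte genes 4 fell and none rose, or 5 when adjusted over the list alone (median log2 fold change −0.98, adjusted p = 0.0246; adjusted p = 0.307 with an estimated correlation). This call was lost without AML1/ETO library 2 (adjusted p = 0.258, in a range from 0.00284 when a library was left out). The fractalkine receptor gene Cx3cr1 was at least 82.6-fold lower, and lysozyme, Lyz2, 2.80-fold lower. Of 7 T and NK cell genes 3 fell and none rose, also 3 when adjusted over the list alone (median with genes at 0 held at their bound −2.65, adjusted p = 0.0338; adjusted p = 0.307 with an estimated correlation). It was not called without AML1/ETO library 2 or 3 (adjusted p = 0.0714 and 0.0551, in a range from 0.0220 when a library was left out). Nkg7, a cytotoxic granule gene, fell to 5.16 from 77.7 CPM. Of 9 B and plasma cell genes 6 fell and none rose, also 6 when adjusted over the list alone (median with genes at 0 held at their bound −3.45, adjusted p = 0.0134; adjusted p = 0.307 with an estimated correlation). Cd72 fell 6.13-fold, and the B cell factors Ebf1 and Pax5 were at least 19.9-fold and 16.6-fold lower. The control means of Ebf1, Pax5 and Cxcr2 were only 4.05, 3.38 and 3.93 CPM. Of 518 genes at 1 to 5 CPM in the controls and at 0 in every AML1/ETO library, loss of scarce transcripts would give 117. The least folds of these 3 genes are therefore not firm limits.

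The erythroid, megakaryocyte, dendritic cell and stromal lists were not called by camera. Fry called the erythroid (adjusted p = 0.0473), megakaryocyte (0.0004365) and dendritic cell (0.00639) lists lower. Of 15 erythroid genes 1 rose and 5 fell, or 2 and 6 when adjusted over the list alone (adjusted p = 0.403). The beta-globin Hbb-bt rose to 25.9 ± 31.3 CPM, or 8.11 CPM without AML1/ETO library 3, with control reads in control library 2 alone. Gfi1b, an erythroid and megakaryocytic repressor, fell 19.3-fold. Hbb-bt is close in sequence to Hbb-bs, and reads shared by the pair could have been split in counting. Of 15 megakaryocyte genes 2 rose and 6 fell, or 2 and 7 when adjusted over the list alone (adjusted p = 0.0809). It passed as lower without AML1/ETO library 1 or 3 (adjusted p = 0.0385 and 0.0401, in a range up to 0.160 when a library was left out). Cd9, a tetraspanin of platelets, fell 11.4-fold. Of 11 dendritic cell and MHC class II genes 1 rose and 5 fell, with the same counts when adjusted over the list alone (adjusted p = 0.116). This list too passed as lower without AML1/ETO library 1 or 3 (adjusted p = 0.0385 and 0.0429, in a range up to 0.160 when a library was left out). The integrin gene Itgax was at least 34.1-fold lower and H2-DMa, which loads peptides on MHC class II, 1.83-fold higher. Of 9 stromal and endothelial genes 2 rose and 3 fell, with the same counts when adjusted over the list alone (adjusted p = 0.593). Pdgfrb, a PDGF receptor, rose 3.38-fold and Spp1, osteopontin, fell to 0.521 CPM, or at least 83.8-fold without AML1/ETO library 2.

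Genes of DNA replication fell together: 19 of 22 fell and none rose, or 21 when adjusted over the list alone. The list was called lower (median log2 fold change −1.73, adjusted p = 1.54e-09; adjusted p = 0.307 with an estimated correlation). Rrm1, a subunit of ribonucleotide reductase, fell 3.69-fold to 61.9 ± 27.7 CPM from 229 ± 23.3 CPM (log2 fold change −1.89, SE 0.25, adjusted p = 0.000274). Mcm7, part of the replicative helicase, fell 2.82-fold and Pole, a DNA polymerase, 4.03-fold, while Pcna stood at 363 against 348 CPM (adjusted p = 0.838). Of 22 mitosis genes 14 fell and none rose, or 15 when adjusted over the list alone (median log2 fold change −1.43, adjusted p = 1.43e-05; adjusted p = 0.307 with an estimated correlation). Mki67, the proliferation marker Ki-67, fell 3.04-fold to 208 ± 73.7 CPM, and the mitotic kinesin Kif11 fell 3.64-fold. Of 22 DNA repair genes 1 rose and 6 fell, with the same counts when adjusted over the list alone, and the list was not called (adjusted p = 0.132). Lig1, the replicative DNA ligase, fell 4.92-fold and the mismatch repair gene Msh6 3.77-fold. Of 18 CDK inhibitor and p53 target genes 2 rose and 2 fell, or 3 and 2 when adjusted over the list alone (adjusted p = 0.831). Btg2, an antiproliferative gene, rose 14.9-fold to 1188 ± 258 CPM, and Sesn2, a stress-induced metabolic regulator, fell 4.92-fold.

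Hox and cofactor genes were called lower (median log2 fold change −1.46, adjusted p = 0.0258; adjusted p = 0.307 with an estimated correlation). Of 15 tested members 5 fell and 1 rose, or 7 and 1 when adjusted over the list alone. Hoxa10 fell to 0.371 from 24.1 CPM, with reads in AML1/ETO library 3 alone, without which it was at least 116-fold lower. Hoxb4, a regulator of stem cell self-renewal, fell 3.10-fold, whereas Meis1, a Hox cofactor, rose 2.10-fold. Of 10 tested genes associated with t(8;21) leukaemia 3 rose and 4 fell, with the same counts when adjusted over the list alone, and the list was not called (adjusted p = 0.486). Besides Runx1t1, Cd48 rose 6.34-fold, and Ubash3b, a phosphatase that dampens receptor signalling, fell 4.60-fold. Of 27 interferon response genes 5 rose and 1 fell, or 4 and 1 when adjusted over the list alone (median log2 fold change 0.09, adjusted p = 0.403). Ddx60 rose 4.12-fold and Stat2, a mediator of interferon signalling, 3.64-fold, while Irf9 stood at 58.5 against 57.5 CPM.

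**Figure D3:**
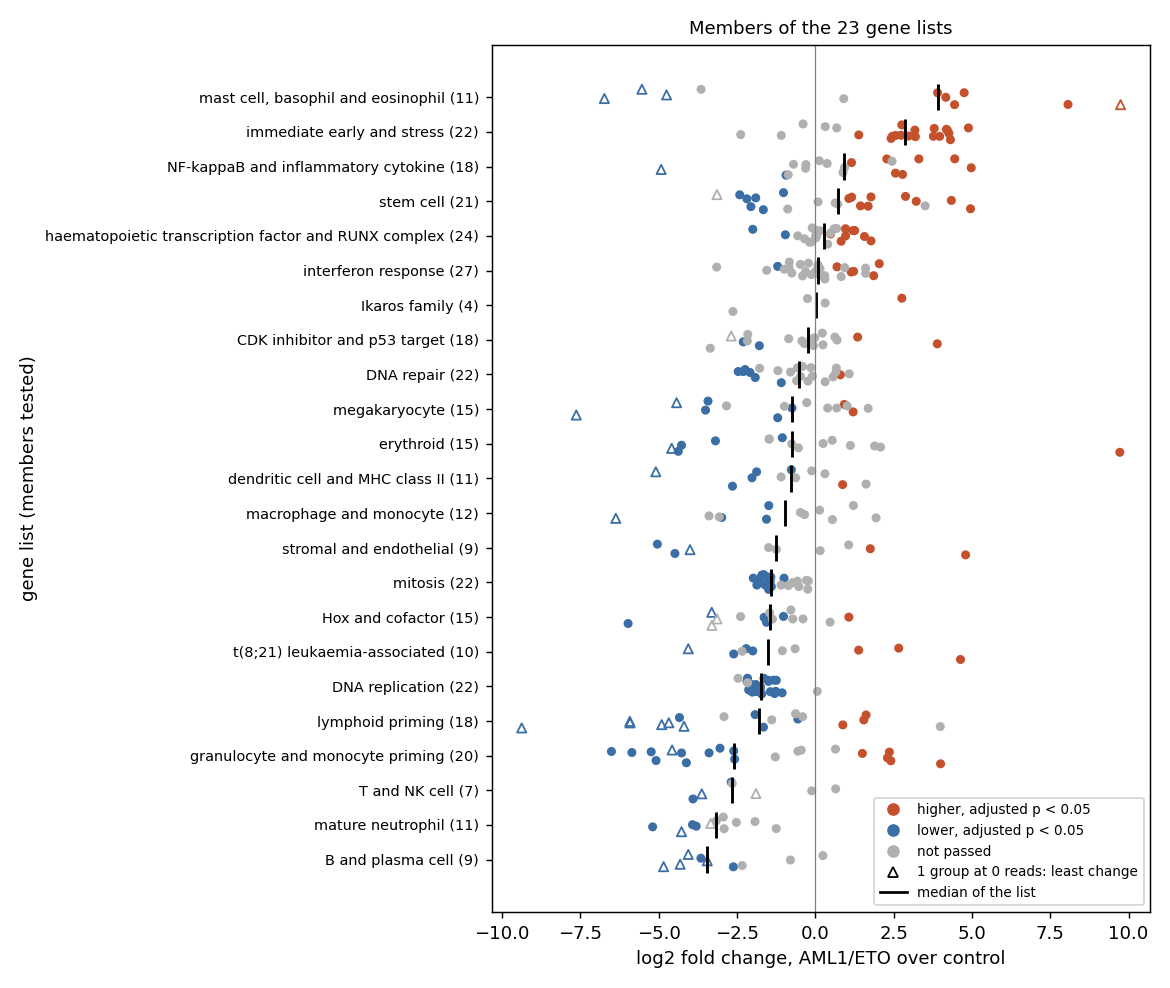
Log2 fold change of AML1/ETO over control (horizontal axis) for each tested member of the 23 gene lists (vertical axis, number tested in brackets), with the median of each list as a black line. Red and blue points passed the test as higher or lower, grey points did not, and open triangles mark genes at 0 reads in a group, drawn at their least change. The immediate early list has its median at 2.87 and the DNA replication list at −1.73.

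As limits, no list was called with an estimated correlation (1 passed as higher and 2 as lower at an unadjusted p under 0.05), and every list except the immediate early and DNA replication lists gave as small a p in 5 or more of the 56 ways to set 3 libraries against 5. Genotype was tied to the Xist and Y-linked pattern in all 8 libraries. Of the 109 genes that the naming rule took, 29 overlap another tested gene, introns included. Some, such as Satb1, Rag1 and Meis1, overlap a gene on the same strand, so strand would not separate reads where exons coincide. For overlaps on opposite strands, reads could not be told apart if strand was not used.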

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

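The tests of the regroupings, of the sex-linked pattern, of autosomal genes, of heat shock, of the sorting day and of the region around Runx1 were chosen after the results were seen; those of dropout and of a lone aberrant library were fixed before their deciding values were computed. Among the 5 controls, 10 of 115 items had a library far from the others by Dixon's ratio, where chance gives about 1 in 20. Ribosomal protein genes took 8.06% of counts in control 3 and 6.32% to 6.78% in the other controls (ratio 0.737). Control 5 was high for Runx1 (201 CPM, others 131 to 151; ratio 0.711). Control 4 was high for Cbfb (166 CPM, others 145 to 151; ratio 0.717), Plek (696 CPM, others 589 to 617; ratio 0.736) and Sparc (4.13 CPM, others 0 to 0.819; ratio 0.802). Control 3 was high for Gfi1 (33.9 CPM, others 8.48 to 15.02; ratio 0.743) and Nkg7 (114 CPM, others 60.9 to 74.8; ratio 0.740). Control 1 was high for Csf2rb (150 CPM, others 74.9 to 91.9, ratio 0.774), and control 2 for Mn1 (34.7 CPM, others 22.2 to 25.1, ratio 0.767) and Hbb-bt (0.117 CPM, others 0, ratio 1). The ratio is always 1 when all other libraries are at 0, and Hbb-bt had 2 control reads, so its flag carries no weight.

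The real grouping gave more called genes than any other, which alone does not exclude chance. A share of 1 of 56 is the smallest that these groupings can give. Every other grouping mixes AML1/ETO and control libraries in at least 1 set, which widens the spread within it and leaves few genes to call. Only 1 of the 56 ways to set 3 libraries against 5, the real one, gave 1734 or more genes higher, and 1 gave 2128 or more lower; the highest of the other 55 was 0 in each direction with edgeR (444 higher and 1135 lower at an unadjusted p under 0.05, against 2364 and 3343 for the real grouping). For lists, the real grouping gave 9 called lower, more than the highest other, 8, so that 1 of 56 was as large. It gave 4 called higher where another gave 9, and 11 of 56 gave as many. Of the 10 others, 7 put all AML1/ETO libraries in the set of 5 and so hold the real difference in mirror image. Without the 10 groupings of that kind, 4 of 46 gave as many (highest other 5), so chance cannot be excluded for the number of lists called higher. By list, the immediate early genes reached so small a p in 1 of 56 groupings and DNA replication in 2, and the other 11 called lists in 5 to 16 (3 to 11 of the 46).

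Sex is a rival explanation to genotype. The pattern of Xist and 4 Y-linked genes held in all 8 libraries as in female AML1/ETO and male control mice; the lowest Xist level in an AML1/ETO library, 1972 CPM, argues against male cells that had lost the Y chromosome. With X and Y left out, 3745 genes were called, so a sex effect limited to them is not the whole cause. Genotype alone could give these calls, so their number does not show whether sex acted beyond X and Y. Sex-dependent expression of autosomal genes cannot be told apart from genotype, since the number of libraries in which sex and genotype were not tied was 0. How much of each change belongs to genotype and how much to sex stays open.

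Many genes had no read in any AML1/ETO library. Each library's own rate of dropout (transcripts lost from small amounts of RNA) predicts 9.33e-05 such genes among those with a control mean of 20 CPM or more, and 23 were seen (exact 95% Poisson interval 14.6 to 34.5). At 5 to 20 CPM it predicts 1.43, and 112 were seen (92.2 to 135). Dropout in independent libraries is thus argued against as the whole cause for these classes, while at 1 to 5 CPM it would give 117 of the 518 seen. The prediction treats dropout as independent of the gene, so a loss tied to particular transcripts stays open, as do genotype and sex.

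The median of the immediate early list was above the control mean in every AML1/ETO library. A lone aberrant library is argued against by the lowest of the 3 library medians, 2.59 on the log2 scale over the control mean. A heat shock response during handling would raise chaperones alongside, but their median log2 fold change was −0.298 (MAD 0.898), below the 2.87 of the immediate early list. A sorting or preparation day shared by the AML1/ETO mice cannot be told apart from genotype, since 0 libraries carry a day in their labels, and handling that spares chaperones may also act this way. An effect of the fusion or of sex stays open as a hypothesis.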

How the results depend on the processing

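The settings without genes on X and Y, without both first libraries and with a mean of 20 CPM or more were chosen after the data were seen. Except with the replicate block, counts stayed within 1.5 times the reported ones under every alternative: 1213 to 2295 genes higher and 1468 to 2712 lower, with 1385 to 1752 and 1537 to 2287 when a library was left out; without both first libraries 1760 and 2350, of which 1464 and 1754 were among the reported genes. DESeq2 gave 2295 and 2681. Ikzf2 (log2 2.54 to 2.93) and Runx1t1 (4.39 to 5.10) passed in every fit, the same ranges as when a library was left out. The labels do not say whether replicate numbers pair the libraries. Correlations of deviations were small (0.039, −0.039 and 0.027 for numbers 1 to 3). The second principal component set both first libraries apart, so a batch shared by number 1 is not excluded. With the number as a block, 951 genes were higher (940 of the reported ones) and 1098 lower (1079). Ikzf2 was then 2.77 and Runx1t1 4.96. With this block 5 lists were called higher and 8 lower. Stem cell genes gained a call (camera adjusted p = 0.0413) and granulocyte and monocyte priming lost its own (0.0703). Of the genes that the naming rule took 14 lost their call with the block, 12 with limma-voom and 1 with DESeq2 (Ngp). Chil3, Ngp, Ctss and Il2rb lost theirs in most fits without a library. Runx1 gained one without AML1/ETO library 1, alone (0.78) or with control 1 (0.73), and Cbfb without AML1/ETO library 2 (−0.97). Ikzf5, not called, turned to −1.27 without AML1/ETO library 3 (range 1.15 to −1.27 when a library was left out). Lists called higher numbered 3 to 5 and lower 7 to 11 when a library was left out. With an estimated correlation 0 were called higher and 0 lower, and with fry 6 and 14. The CDK inhibitor and p53 list, not called, changed direction without control 1 (adjusted p = 0.857) and control 3 (0.957), within a range of 0.712 to 0.957 when a library was left out. The cause of these changes was not tested. Fits that leave libraries out also have fewer samples, and this was not separated from which library was left out. At this depth genes near 3 reads per library cannot be read as absent. The same holds well above that floor. Of genes with 50 to 100 expected reads, 14.85% to 21.82% were at 0 in the single AML1/ETO libraries, so folds given as at least a value are not firm limits.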

Other observations

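The 12 lists here and the test around Runx1 were chosen after the fold changes were seen, and adjusted p-values are over 9 of these lists. The adjustment does not correct for that choice, so these p-values only describe the lists. Genes that ATF4 induces under amino acid stress were lower, with 13 of 20 fallen and 2 risen (median log2 fold change −1.72, camera adjusted p = 2.055e-05; adjusted p = 0.08025 with an estimated correlation). Phgdh, the entry enzyme of serine synthesis, fell to 54.5 ± 20.5 CPM from 311 ± 31.5 CPM, and Mthfd2, a mitochondrial folate enzyme, to 4.46 ± 5.01 from 73.5 ± 3.64 CPM (1.599 CPM without AML1/ETO library 2). Of 21 cholesterol synthesis genes 7 fell (adjusted p = 0.01395; adjusted p = 0.137 with an estimated correlation), among them Cyp51 at 4.17 against 91.4 CPM (1.29 CPM without AML1/ETO library 2). Of 85 nuclear genes of oxidative phosphorylation 20 fell (adjusted p = 0.000317; adjusted p = 0.577 with an estimated correlation), of 12 mitochondrially encoded genes 3 fell (adjusted p = 0.0358; adjusted p = 0.577 with an estimated correlation), and of 38 histone genes 1 fell (adjusted p = 0.0230; adjusted p = 0.577 with an estimated correlation). Glycolysis (2 rose and 5 fell of 17, adjusted p = 0.3802), heat shock chaperones (2 and 3 of 14, adjusted p = 0.539) and ribosomal proteins (1 and 2 of 81, adjusted p = 0.539) were not called.

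The GIMAP GTPases, a gene cluster best known from lymphocytes, went against the lower lymphoid genes: 7 of 8 rose (median log2 fold change 2.27, adjusted p = 5.30e-07; adjusted p = 0.08025 with an estimated correlation), led by Gimap4 at 171 ± 36.3 against 7.61 ± 1.64 CPM. The next 3 lists were built around genes already seen to change, so no p-value is given for them and their counts only describe them. Of 4 tested Ly6 genes 3 rose and 1 fell: Ly6c1 rose to 127 ± 120 from 0.188 ± 0.388 CPM (to 62.7 CPM without AML1/ETO library 3, or from 0.0146 CPM without control library 2), while its near-identical neighbour Ly6c2 fell to 1.38 from 53.3 CPM (0.883 CPM without AML1/ETO library 2, 2.07 CPM without library 1), and reads of the pair could not be told apart where their sequences match. Of 11 type 2 cytokine receptor and mast cell progenitor genes 7 rose and 2 fell, with Il1rl1, the IL-33 receptor, at 483 ± 178 against 2.83 ± 1.31 CPM. Of 11 complement genes 4 rose and 2 fell, with C4b at 802 ± 268 against 2.78 ± 1.44 CPM.

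Sequence carried along with a targeted allele may change genes near Runx1 on chromosome 16; this hypothesis was tested within 10 Mb of the gene. Of 82 tested genes there 25.6% were called (exact 95% interval 16.6% to 36.4%), against 25.7% of all other genes (one-sided Fisher's exact p = 0.552), which gives no excess. The test assumes that the allele lies at Runx1, and its sequence is not given. A share of called genes also could not show a change in a few of them.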
